A study of Drosophila melanogaster with 6 samples.

How the data were processed

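The study measured gene expression in the heads of male Drosophila melanogaster with 1-colour Affymetrix expression arrays. Per the labels, males were kept for 6 days after eclosion either alone, 1 fly per vial, or in groups of 10 flies per vial, and each sample was RNA from 20 heads. There were 3 arrays of single-housed and 3 arrays of group-housed males, which the labels describe as biological replicates. All 6 arrays were mapped to a group and used.

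The deposited values were signal intensities on a linear scale, 1 per probe set and array, from 0.0284 to 11378. The algorithm that summarised the probes, its background correction and any scaling the authors applied are not given in the sources used here, and the arrays as deposited did not share 1 scale. The median deposited intensity per array ran from 24.2 to 31.6, and the mean between the 2nd and 98th percentile from 133 to 176. The 100 brightest probe sets held 14.3% to 15.2% of the intensity of an array. The precision is limited by the number of arrays, since an intensity carries no count behind it.

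The table held 18952 probe sets, of which 183 were control probe sets and were left out. Of the other 18769, the platform annotation gave 1 gene for 13647, several genes for 402 and no gene for 4720. Names were checked by gene ID against the gene table of assembly Release 6 plus ISO1 MT, where 13544 of the 13647 matched and 0 names needed updating. No gene was named from a probe set with several genes, and no genome coordinates are given because no genome sequence was used here.

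Values were taken as log2(intensity + 16). Because the array medians on that scale differed by 0.24, more than the limit of 0.2 set beforehand, the arrays were quantile normalized. The 30% of probe sets with the lowest mean over all 6 arrays were left out, which left 13138. Single-housed and group-housed arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of adjusted p 0.05. All tests were 2-sided, and every difference is single-housed minus group-housed. Fold values are on the log2(intensity + 16) scale and understate the change of dim probe sets. The median residual SD was 0.156 on the log2 scale. Correlations between arrays after normalization ran from 0.977 to 0.989 across probe sets, which are not independent replicates, and no 2 arrays held the same values. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1.

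The design, the tests between the housing groups, the alternatives and 31 gene lists were fixed before the data were examined. Of the tests of explanations in the closing part, some were chosen later and are named there. Changes of sign of a list are judged by its median, which was also chosen later. The lists cover the cytochrome P450 family, glutathione S-transferases and UDP-glycosyltransferases, odorant binding proteins, chemosensory receptors, pheromone detection, antimicrobial peptides, immune recognition, Turandot genes, heat shock proteins, oxidative stress defence, biogenic amines, neuropeptides, the circadian clock, sex determination, courtship and aggression, cuticular hydrocarbon synthesis, digestion and the starvation response, gut serine proteases, immediate early genes, phototransduction, neurons, glia, head fat body, hemocytes, muscle, cuticle, male accessory gland and testis, salivary gland, ribosomal proteins, oxidative phosphorylation and the proteasome. After the data were seen, 1 gene caught by a symbol pattern was taken out of each of 2 lists because it is a different gene, headcase from the biogenic amine list and Prosap from the proteasome list. Each gene entered once, through its probe set with the highest mean, which gave 9604 genes. The 29 lists with at least 5 genes tested were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members were also counted with adjustment over the list alone. Camera with an estimated correlation and fry were run as alternatives.

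The genes named follow a rule. Cyp6a20 comes first, since the published study of this comparison is about it. Next come up to 15 genes per direction past adjusted p 0.05 with non-overlapping groups. Each direction is filled to 12 with the smallest p among genes with non-overlapping groups and a log2 difference of at least 0.58 in size. For each list, up to 4 members with the smallest p may be named, and genes known only by a CG number may be left out. Other genes appear only where they are said to have been chosen after their values were seen, or as members of the marker and target lists of the closing part.

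The alternatives were the deposited scaling, median centring, pseudocounts of 1 and 64, no filter, a filter at 50%, eBayes without the trend, robust eBayes (with statmod 1.5.0), array weights, the replicate number as a block, each array left out in turn, thresholds of adjusted p 0.1 and unadjusted p 0.05, 1 probe set per gene, removal of probe sets that can cross-hybridize, and a gene's mean over its probe sets. The procedure was tested on 10 simulated versions of this comparison with 13138 probe sets and 200 changed in each. It found 72.0% of the changes of log2 size 1 and 83.9% of those of size 2, with 3.82% false among the calls. A list of 20 genes shifted by 0.3 was called in 10 of 10 draws. That shift exceeds the medians of all lists called below, the largest of which was 0.21 in size. The draws therefore do not show how often shifts of the reported size are found. The simulated probe sets varied independently, so the draws could not test calls of lists whose genes vary together. In the real data the estimated inter-gene correlation was 0.40 for the proteasome list. Plots were drawn with matplotlib 3.10.9.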

Results

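Head RNA of male flies was profiled after 6 days of contrasting social experience. Males lived either alone or in groups of 10, and the series describes the single-housed males as the more aggressive of the pair. Each housing condition was represented by 3 arrays of 20 pooled heads. The comparison asks which head transcripts differ with social experience. All differences are given on the log2 scale as single-housed minus group-housed, with the standard error (SE) of the limma fit and n = 3 arrays per group.

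Cyp6a20 encodes a cytochrome P450 that is known for its part in the effect of social experience on male aggression. Its signal was 1.18-fold higher in group-housed heads (95% interval 1.03 to 1.35), a log2 difference of -0.24 (SE 0.086). The normalized log2 signal was 7.93 ± 0.092 in single-housed and 8.17 ± 0.043 in group-housed heads (SD, n = 3). After normalization all 3 group-housed arrays lay above all 3 single-housed arrays. The exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. In the fit over all 13138 probe sets, limma gave an adjusted p of 0.546, so the difference did not pass the threshold. As deposited, before any common scaling, the signals were 249.7, 237.2 and 225.9 in single-housed and 279.9, 227.7 and 271.1 in group-housed heads. These overlap, with means of 238 ± 11.9 and 260 ± 27.9 (SD, n = 3). The log2 difference with the deposited scaling was -0.12, and the adjusted p ran from 0.354 to 0.991 over the alternatives. By p, Cyp6a20 ranked 16 among the 73 P450 genes tested, and it was measured by 1 probe set.

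Gene by gene, 2 probe sets passed the threshold. CG6839 rose in single-housed heads (log2 3.94, SE 0.41, adjusted p 0.0401). Its group-housed mean of 4.85 lay near the filter cutoff of 4.69, so the size depends on the added intensity, with log2 differences of 4.96 and 2.69 for pseudocounts of 1 and 64. The probe set 1637290_at, for which the annotation lists no gene and which is named here after its values were seen, fell by 0.71 (SE 0.067, adjusted p 0.0352), 1.64-fold lower, with group values of 9.87 ± 0.063 and 10.58 ± 0.026 (SD, n = 3). Neither call held throughout. CG6839 kept it in 8 of 16 alternatives (limma adjusted p 3.85e-06 to 0.314) and lost it with a pseudocount of 64, without a filter, with the filter at 50%, without the intensity trend, with robust eBayes, and without single-housed replicate 3 or group-housed replicate 1 or 3. The probe set 1637290_at kept it in 10 of 16 (adjusted p 0.0178 to 0.291) and lost it with the deposited scaling, with median centring, without the intensity trend, and without single-housed replicate 1, 2 or 3. The genes with the smallest p after these were mostly higher in value in single-housed heads. Pepck2, a phosphoenolpyruvate carboxykinase of gluconeogenesis, had a 3.55-fold higher signal (log2 1.83, SE 0.21, adjusted p 0.0592). CG14125 was at 5.51 (SE 0.75, adjusted p 0.0854), with 6.49 without group-housed replicate 1 and 4.79 without group-housed replicate 2. CG7567 was at 4.11, CG10910 at 3.09 and CG15043 at 2.87 (adjusted p 0.0854, 0.0762 and 0.126). Group-housed values spread from 4.46 to 7.88 for CG14125 and from 4.22 to 6.33 for CG7567, and the group-housed means of CG10910 and CG15043, 4.91 and 4.93, lay near the cutoff. Over the alternatives the differences of these 4 genes ran from 4.52 to 6.49, 2.92 to 5.32, 1.99 to 3.99 and 1.83 to 3.74. CG15199 was at 1.06. Bcat, a branched-chain amino acid aminotransferase, was at 0.79 (SE 0.12), the homeobox gene Dr at 1.22 (SE 0.19), and Akh, the adipokinetic hormone that mobilizes stored energy, at 0.59 (SE 0.098, adjusted p 0.158). CG11741 and CG32444 were at 1.28 and 0.66.

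On the other side, the antimicrobial peptide genes DptB and Mtk had 6.85-fold and 5.51-fold lower signals in single-housed heads (log2 -2.78, SE 0.62, and -2.46, SE 0.65, adjusted p 0.334 and 0.431). With 1 array left out they ran from -3.46 to -1.93 and from -3.21 to -1.88. The P450 gene Cyp4p2 was at -0.65 (SE 0.15). Ama, an immunoglobulin-domain protein of the nervous system, was at -0.73, and CheA87a, of a chemosensory protein family, at -0.74 (SE 0.21). The probe set chosen for side-V was at -0.80 and its other probe set at 0.00. Among genes known only by number, CG33109 was at -1.92, CG4269 at -1.22, CG14022 at -0.88, CG34212 at -0.81, CG13064 at -0.74 and CG10383 at -0.59. None of these 12 passed the threshold. The single-housed means of Ama, side-V, CG33109, CG34212 and CG13064, from 4.35 to 4.75, lay near the filter cutoff of 4.69. Their sizes depend on the added intensity. With pseudocounts of 1 and 64 Ama was at -1.38 and -0.30, and CG33109 at -2.84 and -1.06.

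**Figure D1:**
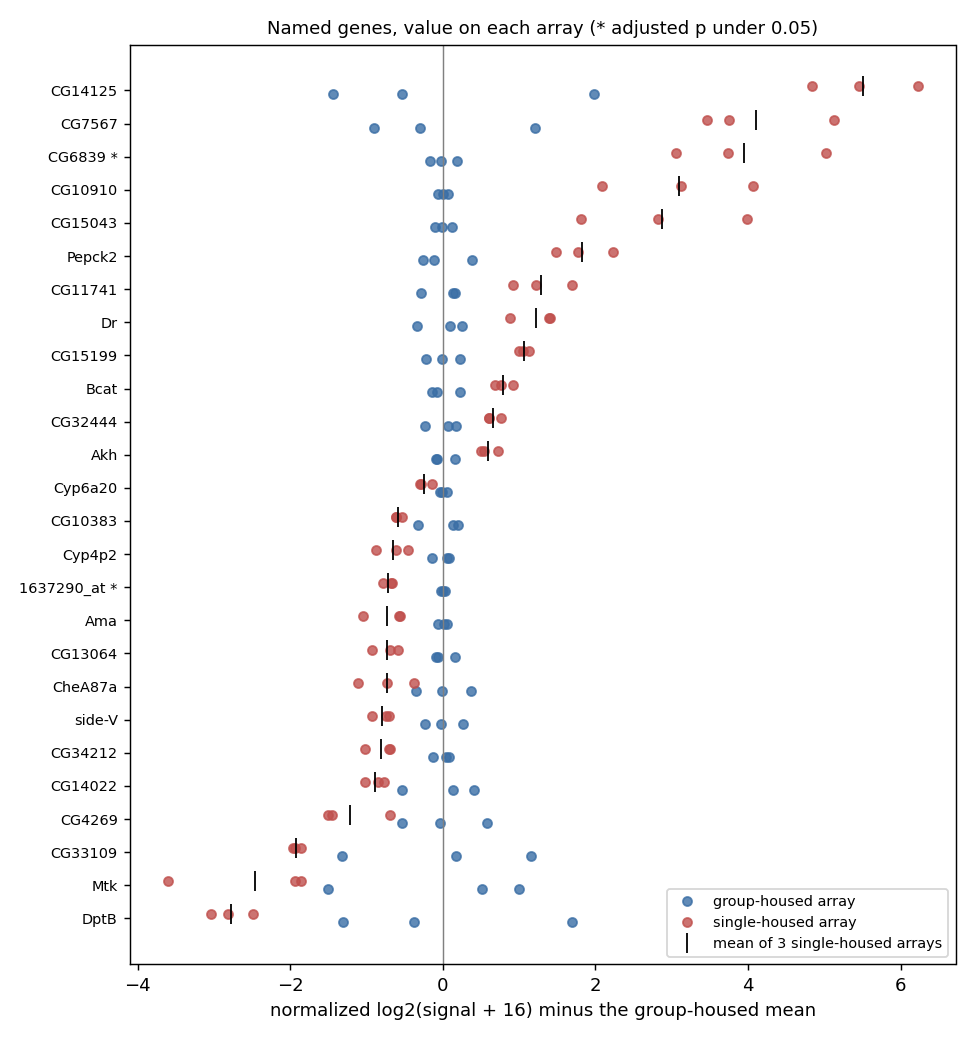
Normalized log2(signal + 16) of each named gene on each array, minus the mean of the group-housed arrays, with single-housed arrays in red and group-housed arrays in blue. The black tick is the mean of the 3 single-housed arrays; CG6839 and the probe set 1637290_at, marked with a star, passed adjusted p 0.05, and Cyp6a20 lies at -0.24.

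At adjusted p 0.1 there were 8 probe sets, 7 of them higher in single-housed heads. At unadjusted p 0.05 there were 1082, with 600 higher and 482 lower (55.5% higher). If no probe set differed, 657 would be expected, and the 9 other splits of the arrays into 3 and 3 gave 279 to 1012. The groups did not overlap for 1863 probe sets (14.2%), where chance gives 10%. The count of calls depended on how the arrays were scaled. With the deposited scaling 78 probe sets passed, 69 higher and 9 lower, and 94.1% of those at unadjusted p 0.05 were higher. Median centring gave 11, all higher, and 74.9%. The median over all probe sets was 0.099 with the deposited scaling and -0.017 after quantile normalization. Single arrays also set the count. Without group-housed replicate 2 there were 47 calls, without group-housed replicates 1 and 3 there were 7 and 9, and without single-housed replicates 1, 2 and 3 there were 6, 1 and 0 (limma, with 1045 at unadjusted p 0.05 in the last case).

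Of the 29 gene lists tested, 15 differed from all other genes at camera adjusted p 0.05 with the preset correlation, 10 toward single-housed and 5 toward group-housed heads. With an estimated correlation camera called 0 lists, and 4 at unadjusted p 0.05. A higher correlation does not account for this alone. For the courtship and aggression and the hemocyte lists the estimates, 0.0019 and -0.017, lay below the preset 0.01. Their unadjusted camera p still rose from 0.0097 to 0.0484 and from 0.00444 to 0.0361. Directional fry also called 0, and 5 at unadjusted p 0.05, while fry for changes in either direction called 11. With the deposited scaling the medians of the 10 lists called higher lay between 0.18 and 0.34, above those given below. The median over all probe sets was also higher in that setting, at 0.099 against -0.017. The 2 probe sets past the threshold in limma belong to none of the lists, so the single members below are given as values unless they passed with adjustment over the list alone. That adjustment does not allow for the number of lists, and no member passed with adjustment over all probe sets.

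**Figure D2:**
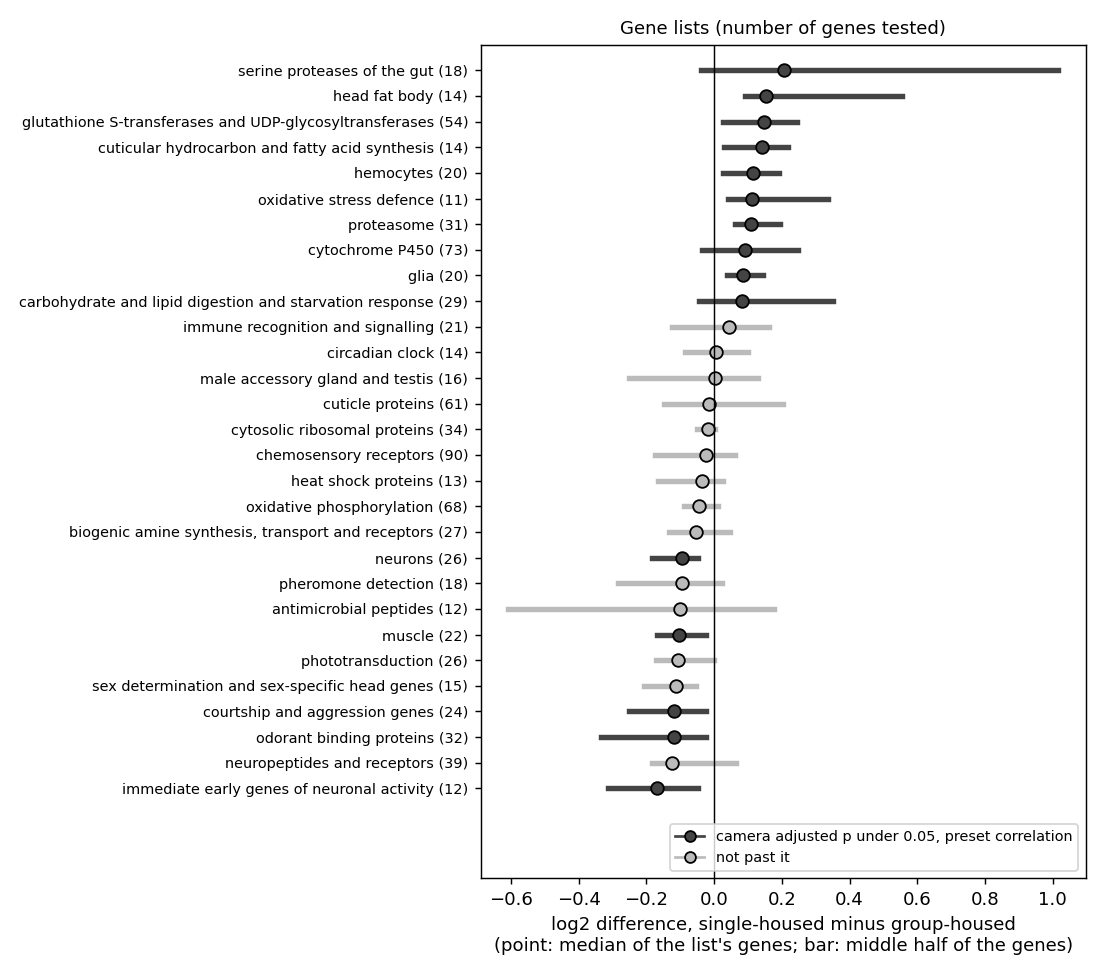
Median log2 difference, single-housed minus group-housed, of each gene list (point) with the middle 50% of its genes (bar) after quantile normalization, and the number of genes tested in brackets. Dark points are the 15 lists past camera adjusted p 0.05 with the preset correlation, and with the deposited scaling the medians of the odorant binding protein, courtship and aggression, neuron and muscle lists lie above 0. In that setting the median over all probe sets is 0.099.

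Genes of the fat body, the fly's liver-like and adipose tissue, stood higher in single-housed heads. The head fat body list had a median of 0.15 over 14 genes, 13 of them above 0 (camera adjusted p 2.29e-05, adjusted p = 0.402 with an estimated correlation). In it, fit and Obp99b rose with adjustment over the list alone. The gene fit, which encodes a peptide secreted by the fat body, was at 1.39 (SE 0.32, 2.62-fold), and Obp99b at 0.76 (SE 0.13). The lipid droplet gene Lsd-1 was at 0.56 (SE 0.22), and at 0.27 without group-housed replicate 3. In group-housed heads fit ranged widely, with 10.55 on the array of replicate 2 against 9.87 and 8.97 on replicates 1 and 3. Without that array the list median was 0.23.

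The list of digestion and the starvation response had a median of 0.08 over 29 genes (adjusted p 0.0172, adjusted p = 0.424 with an estimated correlation). Pepck2 and the lipase gene Lip2, at 0.74 (SE 0.17), rose with adjustment over the list alone. Pepck1 was at 0.62 (SE 0.19) and the insulin receptor gene InR at -0.46 (SE 0.15). This list lost its call without single-housed replicate 2 or 3 (highest adjusted p 0.132), and its median was 0.054 without group-housed replicate 1 and 0.050 with a pseudocount of 64. Cuticular hydrocarbon and fatty acid synthesis had a median of 0.14 over 14 genes (adjusted p 0.0201, adjusted p = 0.433 with an estimated correlation), with AcCoAS, an acetyl-CoA synthetase, at 0.28 (SE 0.077). Its call was lost with the deposited scaling, with the filter at 50% and without single-housed replicate 3 or group-housed replicate 1, where the medians were 0.077 and 0.083.

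Neuropeptide and receptor genes as a list were not called (median -0.12 over 39 genes, adjusted p 0.212). Within it, Ilp5, an insulin-like peptide of the brain, and Akh rose with adjustment over the list alone, at 0.97 (SE 0.17, 1.95-fold) and 0.59. The neuropeptide genes Pdf and AstC were at -0.30 (SE 0.080) and -0.26 (SE 0.078).

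Serine proteases of the gut had a median of 0.21 and a mean of 0.67 over 18 genes (adjusted p 0.0101, adjusted p = 0.468 with an estimated correlation). Jon65Aiii, yip7 and Jon65Aiv rose with adjustment over the list alone, at 3.24 (SE 0.61), 2.72 (SE 0.53) and 2.42 (SE 0.66), and alphaTry was at 2.52 (SE 0.86), or 1.63 without group-housed replicate 2. The groups overlapped for Jon65Aiv, with 7.11 on single-housed replicate 1 and 7.19 on group-housed replicate 1 (limma adjusted p 0.431 over all probe sets). The other 14 members did not reach unadjusted p 0.05, and 7 of the 18 lay below 0. The arrays within a group spread widely, as the SD of 2.07 for alphaTry in group-housed heads shows. The median of the list moved with the settings, from 0.11 with a pseudocount of 64 to 1.17 with the filter at 50%. It was 0.11 without single-housed replicate 2 and 0.035 without group-housed replicate 3. The call was lost without group-housed replicate 3 (adjusted p 0.296) or single-housed replicate 3 (adjusted p 0.0685).

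Detoxification genes stood higher in single-housed heads, as did the head fat body list (median 0.15, 13 of 14 genes above 0). Of 73 P450 genes, 50 lay above 0 with a median of 0.09 (camera adjusted p 0.00015, adjusted p = 0.351 with an estimated correlation). With adjustment over the list alone 8 rose and 2 fell. Cyp4d21, which is known to act in male mating, rose by 0.38 (SE 0.068), Cyp6g2 rose by 0.51 (SE 0.12), and Cyp4p2 and Cyp6t3 were lower at -0.65 and -0.54 (SE 0.13). Cyp6a20 thus lay on the side of the smaller number of P450 genes. Without group-housed replicate 1 the median of the P450 list was 0.059. Of 54 glutathione S-transferase and UDP-glycosyltransferase genes, 42 lay above 0 with a median of 0.15 (adjusted p 2.29e-05, adjusted p = 0.468 with an estimated correlation). None passed over the list alone (0 in limma, 10 higher and 1 lower at unadjusted p 0.05). Without group-housed replicate 3 the median was 0.058 (adjusted p 0.0298). GstE7, GstE6 and GstE9 were at 0.91 (SE 0.19), 0.37 (SE 0.089) and 0.30 (SE 0.083), with the other GstE9 probe set at 0.49. Oxidative stress defence had 10 of 11 genes above 0 (median 0.11, adjusted p 0.00116, adjusted p = 0.351 with an estimated correlation). Cat, which encodes catalase, rose by 0.30 (SE 0.062) with adjustment over the list alone, and the malic enzyme gene Men and the glutathione synthesis gene Gclm were at 0.42 (SE 0.13) and 0.37 (SE 0.12).

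Immune genes went both ways. Antimicrobial peptides as a list were not called (12 genes, median -0.10, mean -0.39, adjusted p 0.212), while the fry test for changes in either direction gave an adjusted p of 0.00335. The median of the list ran from -0.19 to -0.08 with 1 array left out. With adjustment over the list alone DptB and Mtk fell and Drsl2 rose, at 0.62 (SE 0.18), and CecB was at -0.62 (SE 0.26), or -0.33 without group-housed replicate 2. Drsl2 lay near the filter cutoff of 4.69, with means of 5.13 in single-housed and 4.51 in group-housed heads. Its difference ran from 0.23 to 1.41 over the alternatives. In group-housed heads DptB was at 9.79 ± 1.53 and Mtk at 11.36 ± 1.33, against 7.01 ± 0.28 and 8.90 ± 0.99 in single-housed heads (SD, n = 3). Without group-housed replicate 1, which had the highest values, the differences were -1.93 and -1.97. Immune recognition was not called (median 0.04 over 21 genes, or 0.030 to 0.079 with 1 array left out, adjusted p 0.377), with PGRP-SB1 at -0.49 (SE 0.17). Hemocyte markers had a median of 0.11 over 20 genes (adjusted p 0.0143, adjusted p = 0.351 with an estimated correlation), with the phagocytosis-related genes NimB5 and NimC1 at 0.43 (SE 0.11) and 0.27 (SE 0.11). Without group-housed replicate 2 NimC1 was at 0.18. This call was lost with the deposited scaling and without single-housed replicate 1, where the median was 0.067, or group-housed replicate 2. Of the Turandot genes 1 was tested, at 0.17, and with 1 array left out it ran from 0.0099 to 0.28.

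**Figure D3:**
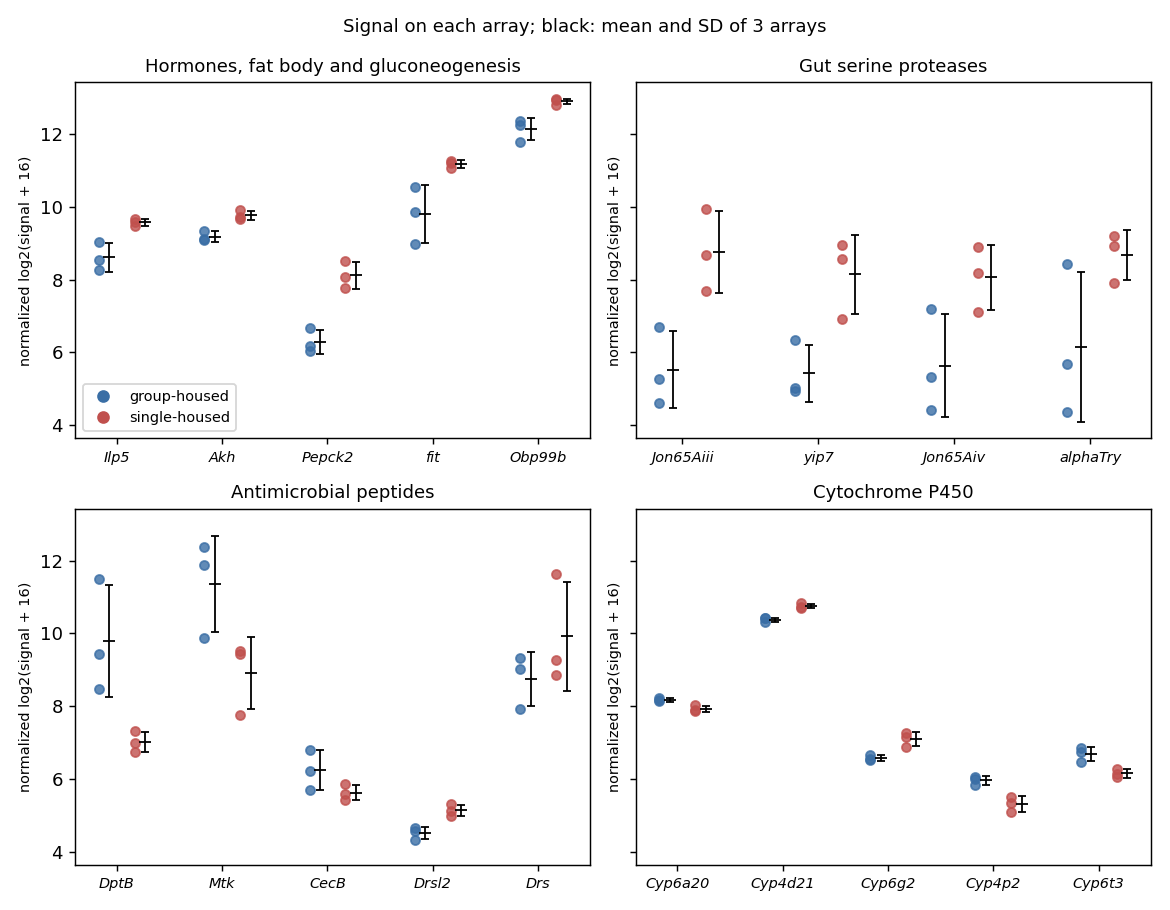
Normalized log2(signal + 16) of selected genes on each array, with group-housed arrays in blue, single-housed arrays in red and the mean with SD of 3 arrays in black. Ilp5, Akh, Pepck2, fit and Obp99b separate the groups, while alphaTry in group-housed heads has an SD of 2.07 and Cyp6a20 differs by -0.24.

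Among lists of the nervous system, those that were called lay lower in single-housed heads, apart from glia. Neuronal markers had 21 of 26 genes below 0 and a median of -0.09 (adjusted p 0.0101, adjusted p = 0.55 with an estimated correlation), but with the deposited scaling the median was 0.066 and the call was lost, as it was with median centring and without single-housed replicate 2 or group-housed replicate 3. The median was -0.15, -0.18 and -0.03 without group-housed replicates 1, 2 and 3. Syn, which encodes synapsin, was at -0.26 (SE 0.11), or -0.15 without group-housed replicate 3, and the sodium channel gene para at -0.22 (SE 0.11). Immediate early genes of neuronal activity had a median of -0.17 over 12 genes (adjusted p 0.0122, adjusted p = 0.468 with an estimated correlation), with the nuclear receptor gene Hr38 at -0.37 (SE 0.11) and its other probe set at -0.16, CG14186 at -0.39 (SE 0.12) and the transcription factor gene sr at -0.43 (SE 0.17), or -0.27 without single-housed replicate 3. This call was lost without single-housed replicate 3 or group-housed replicate 3, where the median was -0.09, and with the deposited scaling the median was -0.03. Courtship and aggression genes had 19 of 24 genes below 0 and a median of -0.12 (adjusted p 0.0201, adjusted p = 0.351 with an estimated correlation), while with the deposited scaling the median was 0.027 and the set test still placed the list below other genes (adjusted p 0.0218). The call was lost with the filter at 50% and without single-housed replicate 3 or group-housed replicate 3. This list includes Cyp6a20, nonA at -0.29 (SE 0.10), the odorant binding protein gene lush at -0.45 (SE 0.23; -0.30 and -0.73 without group-housed replicates 1 and 3), and dsx, the sex determination transcription factor, at 0.39 (SE 0.11). Probe sets disagreed for both nonA, whose others were at 0.01 and -0.09, and dsx, whose other was at -0.11. Glial markers had 17 of 20 genes above 0 and a median of 0.08 (adjusted p 0.016, adjusted p = 0.468 with an estimated correlation). The GABA transporter gene Gat was at 0.40 (SE 0.15), ogre at 0.22 (SE 0.087) and the blood-brain barrier transporter gene Mdr65 at -0.30 (SE 0.095). The glial call was lost without single-housed replicate 1 or group-housed replicate 2, and the median was 0.13 without single-housed replicate 3 and 0.14 without group-housed replicate 1.

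Odorant binding proteins had 25 of 32 genes below 0 and a median of -0.12 (adjusted p 0.031, adjusted p = 0.538 with an estimated correlation), with a median of 0.025 and no call under the deposited scaling. Among other settings, the call was also lost with median centring, without a filter, with the filter at 50%, without the intensity trend, and without single-housed replicate 1 or group-housed replicate 1 or 2. With adjustment over the list alone Obp56g and Obp49a fell, at -0.44 (SE 0.078) and -0.39 (SE 0.084), while Obp99b, also counted in the fat body list, rose. Obp83g was at 0.82 (SE 0.34), and at 0.53 without single-housed replicate 2. Chemosensory receptors (90 genes, median -0.02, adjusted p 0.529) and pheromone detection (18 genes, median -0.09, adjusted p 0.276) were not called, with Ir68b at 0.59 (SE 0.17) and the pheromone receptor gene Or67d at -0.30 (SE 0.16), or -0.19 without single-housed replicate 1. The medians of these lists ran from -0.083 to -0.025 and from -0.181 to -0.062 with 1 array left out. Biogenic amine genes (27 genes, median -0.05, adjusted p 0.343) were not called either. Their members Octbeta1R, an octopamine receptor gene, and DopEcR, a dopamine and ecdysteroid receptor gene, were at -0.35 (SE 0.097) and -0.27 (SE 0.087). Phototransduction had a median of -0.11 over 26 genes (adjusted p 0.0773), with rdgC at -0.24 (SE 0.085) by 1 probe set and -0.0081 by the other. The list median ran from -0.176 to -0.064 with 1 array left out. The circadian clock list had a median of 0.01 over 14 genes (adjusted p 0.805), with 7 above and 7 below 0. It also holds the cell cycle gene twe, at 0.24 (SE 0.13), which is not a clock gene and was not taken out. With adjustment over the list alone cwo, a clock repressor gene, rose by 0.38 (SE 0.081), with its other probe set at 0.21, and Pdf fell. Pdf passed over this list alone (limma adjusted p 0.0357) but not over the neuropeptide list alone (limma adjusted p 0.0662). Sex determination genes had a median of -0.11 over 15 genes (adjusted p 0.298), with fit past the threshold over the list alone and tra at -0.29 (SE 0.089). Their median ran from -0.177 to -0.081 with 1 array left out.

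Of the remaining lists, the proteasome was higher in single-housed heads, with 28 of 31 genes above 0 and a median of 0.11 (adjusted p 2.29e-05, adjusted p = 0.468 with an estimated correlation). Without group-housed replicate 3 the median was 0.036 (adjusted p 0.0253). Rpn6 and Rpn11 were at 0.26 (SE 0.072) and 0.23 (SE 0.078). Muscle genes had 17 of 22 members below 0 and a median of -0.10 (adjusted p 0.0172, adjusted p = 0.468 with an estimated correlation), but with the deposited scaling the median was 0.066 and the call was lost, as it was with median centring and without single-housed replicate 2, where the median was -0.06, or 3, or group-housed replicate 3. With adjustment over the list alone the actin gene Act87E and the myosin light chain gene Mlc1 fell, at -0.37 (SE 0.073) and -0.25 (SE 0.064), and bt was at -0.32 (SE 0.11), or -0.20 without single-housed replicate 2. Heat shock proteins were not called (13 genes, median -0.04, adjusted p 0.276), though DnaJ-1, a co-chaperone gene, fell over the list alone, at -0.35 (SE 0.069), and Hsc70-2 was at -0.37 (SE 0.16), or -0.19 without group-housed replicate 3. Cuticle proteins were not called (61 genes, adjusted p 0.229), and their median of -0.02 differed in sign from their mean of 0.04 and from the set test. Lcp65Aa rose over the list alone, at 1.08 (SE 0.21). Male accessory gland and testis genes (16 genes, adjusted p 0.877) had a median of 0.0028 against a mean of -0.03 and a set test toward group-housed heads. Ribosomal proteins (34 genes, median -0.02, adjusted p 0.257) and oxidative phosphorylation (68 genes, median -0.05, adjusted p 0.0524) were not called. Of the salivary gland genes 2 were tested, with a median of -0.08.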

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

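Of 147 genes, those eligible for naming and those named otherwise, 138 kept their sign in refits with another scaling, pseudocount, filter, variance model, block or set of arrays, of which 9 to 16 kept the gene. With the deposited scaling trpl was at 0.016, Gad1 at 0.029, nrv3 at 0.054, RpS30 at 0.085, RpL17 at 0.085, RpS12 at 0.113 and UQCR-6.4 at 0.061, where the reported values lay below 0, and RpS12 was at 0.026 with median centring. With 1 array left out mex1 ran from -0.063 to 0.115 and Eig71Ee from -0.014 to 0.160. Values moved by over 1.5 times in 61 of the 147 genes with the deposited scaling, in 20 with median centring, in 43 with a pseudocount of 1 or 64 and in 43 with 1 array left out. The number of calls did not hold. The cause was not tested except where the alternative itself changes the number of tests or arrays. In all, higher and lower, limma called 78, 69 and 9 probe sets with the deposited scaling, 11, 11 and 0 with median centring, 5, 4 and 1 with array weights, 8, 7 and 1 at adjusted p 0.1, 1082, 600 and 482 at unadjusted p 0.05, 7, 7 and 0 with 1 probe set per gene, and 4, 3 and 1 without cross-hybridizing probe sets. It called 1, 0 and 1 with a pseudocount of 64, without a filter and with the filter at 50%, and 0 without the intensity trend (985 at unadjusted p 0.05). Robust eBayes gave 2, of which 1 was shared with the reported calls. Leaving out 1 array gave 0 to 47 calls, 0 to 41 higher and 0 to 7 lower, where an arm of 2 arrays shares the pooled spread. Lists called numbered 12 to 16 over the settings with the preset correlation, 9 (without single-housed replicate 3) to 13 with 1 array left out, and 0 with an estimated correlation (4 at unadjusted p 0.05) or directional fry (5). The P450, glutathione S-transferase and UDP-glycosyltransferase, oxidative stress, head fat body and proteasome lists kept their calls in 10 of 10 settings and with each of 6 arrays left out, but not the size of their medians. These ran over the settings from 0.062 to 0.206, 0.128 to 0.311, 0.094 to 0.316, 0.144 to 0.340 and 0.087 to 0.282, and with 1 array left out from 0.059 to 0.117, 0.058 to 0.199, 0.088 to 0.163, 0.135 to 0.234 and 0.036 to 0.137. The gut protease median ran from 0.111 to 1.17 over the settings and from 0.035 to 0.268 with 1 array left out. The cuticular hydrocarbon median was 0.236 and 0.067 with pseudocounts of 1 and 64. Cyp6a20 ran from -0.29 to -0.12 and was never past the threshold.

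Replicate numbers were tested as a block, although the labels do not say what the number stands for, so whether it pairs the samples is not known. Deviations from the group means correlated across probe sets at 0.032, 0.114 and 0.329 for numbers 1, 2 and 3. Between unlike numbers the correlations ran from -0.254 to 0.159, and not every sample correlated best with its own number. The block gave 32 calls, 30 higher and 2 lower, and 15 lists, though not the same ones, since odorant binding proteins lost the call (adjusted p 0.0507) and phototransduction gained it (adjusted p 0.0368). Mtk was among the calls with the block (limma adjusted p 0.00183, against 0.431 without it).

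The median over all probe sets was -0.017 after quantile normalization and 0.099 with the deposited scaling. A positive list median under 0.099 in that setting thus still lay below the median of all probe sets. List medians changed sign as follows. With the deposited scaling they were 0.025 for odorant binding proteins, 0.027 for courtship and aggression, 0.066 for neurons, 0.066 for muscle, 0.031 for chemosensory receptors, 0.0031 for pheromone detection, 0.020 for antimicrobial peptides, 0.097 for heat shock proteins, 0.081 for biogenic amines, 0.035 for sex determination, 0.062 for phototransduction, 0.092 for cuticle, 0.133 for ribosomal proteins and 0.150 for oxidative phosphorylation. In that setting camera placed chemosensory receptors, pheromone detection and antimicrobial peptides below other genes (adjusted p 0.00103, 0.0108 and 0.00263). With median centring they were 0.010 for heat shock proteins, 0.0051 for cuticle, -0.033 for accessory gland and testis, 0.046 for ribosomal proteins and 0.063 for oxidative phosphorylation. Cuticle was at 0.027 without a filter and 0.013 with the filter at 50%, accessory gland and testis at -0.217 with a pseudocount of 1 and -0.0071 with array weights, and the circadian list at -0.015 with array weights. With 1 array left out they ran from -0.029 to 0.079 for cuticle, -0.102 to 0.0019 for biogenic amines, -0.081 to 0.0011 for heat shock proteins, -0.059 to 0.053 for accessory gland and testis and -0.083 to 0.044 for the circadian list. Probe sets near the lowest signals limit what can be compared, since the added intensity of 16 compresses their differences.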

Other observations

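Group-housed replicate 2 lay nearer to the single-housed arrays than the other 2 group-housed arrays did for several metabolic genes, chosen after their values were seen. The glucosidase gene tobi, a target of insulin signalling, read 10.75 on that array against 9.34 and 7.97 on group-housed replicates 1 and 3, and 10.58 to 11.04 in single-housed heads (log2 difference 1.49, SE 0.56, and 0.80 without group-housed replicate 3). Gnmt, a glycine N-methyltransferase gene, read 11.67 there against 10.83 and 10.74, with 11.67 to 11.72 in single-housed heads. Pepck1 read 12.33 against 11.56 and 11.49, and Cyp309a1 8.19 against 6.92 and 7.13. Ugt37B1 read 7.63 against 5.87 and 6.54. Without that array limma called 47 probe sets, Pepck1, Gnmt, Cyp309a1, Ilp5 and Pepck2 among them. Pepck1, Gnmt and Cyp309a1 lay near the single-housed values on that array, so leaving it out widens their differences. Their calls are therefore no separate evidence.

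Antimicrobial peptides did not move as 1 group. The genes of this paragraph were chosen after their values were seen. Drs, which encodes drosomycin, was at 1.16 (SE 0.66, adjusted p 0.688), opposite in sign to DptB and Mtk, and its highest value, 11.62, was on single-housed replicate 1. The difference was 0.31 without that array and 0.74 without group-housed replicate 3. The lysozyme gene LysP was at -1.93 (SE 0.60), with 6.70 and 7.27 on group-housed replicates 1 and 2 and 4.49 on replicate 3. The chitinase gene Cht9 was at 2.30 (SE 0.85), with 8.16 on group-housed replicate 1 and 4.18 and 5.15 on the others, and was at 3.46 and 1.48 without group-housed replicates 1 and 2.

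Of the tests below, those of neuronal tissue and of FOXO were chosen after the result was seen. They replaced earlier forms. The first was the sign of the muscle median (-0.10), which turns with the deposited scaling. The second was a list of 4 FOXO targets with InR, itself part of the pattern. Its median of -0.25 lay at percentile 0.06 among random lists. With the deposited scaling the percentile was 0.46, and so it was with median centring, which shifts all probe sets of an array alike. Of the 10 splits of 6 arrays into 3 and 3, 1 gave as many calls as the real one, the real split itself, with 2 calls against at most 1 in any other. For lists it was also 1 of 10, with 15 lists against at most 13. With 10 splits a share under 0.05 cannot be reached. At unadjusted p 0.05 the real split gave 1082 probe sets and the highest other, with single-housed replicates 1 and 2 and group-housed replicate 2 on 1 side, 1012.

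The gut serine protease list ranked above other genes in single-housed heads with the preset correlation (adjusted p = 0.468 with an estimated one), through 4 of its 18 genes at unadjusted p 0.05, while 7 lay below 0. Whether it rests on the array of single-housed replicate 2, with the highest values, stays open. Without it the list mean was 0.55 against 0.67 with it, which met the bound set beforehand against this explanation. The list also kept its call (adjusted p 0.0261). The mean lay 0.11 above the bound of 0.45, less than its spread over the 18 genes (bootstrap 95% interval -0.0062 to 0.22, added after the result was seen). Gut tissue carried over with the heads stays open. The 3 enterocyte markers tested had a median difference of 0.036, with mex1 at 0.04 (SE 0.16), which met the bound set beforehand against this explanation. That bound was wrong for these arrays, because the highest mean of the 3 markers was 5.13, near the filter at 4.69, where a small share of gut RNA might not be seen. Of the list, 9 members were left out by the filter and read at most 5.36 on any array, and betaTry and Jon25Bi, chosen after their values were seen, read 7.98 and 7.41 on group-housed replicate 1, so gut signal was not limited to single-housed heads. A response of the gut or head to housing was not separable from this. The same question is open for CG6839, which read 7.91, 9.87 and 8.59 on single-housed replicates 1, 2 and 3. Jon65Aiii read 7.69, 9.93 and 8.68 there, but 6.69 against 5.04 for CG6839 on group-housed replicate 1. CG10910 and CG15043 were also highest on single-housed replicate 2 and lowest on replicate 1 among single-housed arrays. This likeness was seen after the values and was not tested.

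The head fat body list ranked above and the neuron list below other genes with the preset correlation (adjusted p = 0.402 and 0.55 with an estimated one). The neuron list lost its call with the deposited scaling (median 0.066, adjusted p 0.188), and 1 of its 26 genes reached unadjusted p 0.05. A lower share of neuronal tissue alone would raise the other cell types alike. The median of the fat body list, itself part of the pattern, lay 0.26 above that of the muscle list (bootstrap 95% interval over genes 0.16 to 0.68). It lay 0.27 above it with the deposited scaling. Median centring shifts all probe sets of an array alike, so it gives the same gap and is no further check. The muscle list thus did not follow the fat body list, but the glia and hemocyte lists, with medians of 0.08 and 0.11, lay on its side. The interval takes genes as independent and does not cover the spread between arrays. A lower neuronal share together with other changes stays open. So do a larger amount of fat body in the sample, a change within it, and social experience itself. For RNA quality, the mean log2 ratio of 3' to 5' control signal differed by -0.067 (SE 0.18). It overlapped between groups, at 0.80 to 1.25 in single-housed and 0.93 to 1.35 in group-housed heads, and the difference was below the bound of 0.2 set beforehand. It lay 0.72 SE from that bound, less than its error, so a difference in quality stays open.

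The insulin receptor gene InR was at -0.46 and Ilp5 at 0.97. A hypothesis is that FOXO, the transcription factor that insulin signalling restrains, may be less active in single-housed heads, since InR is among the genes it activates. The 3 other known targets tested, Lip4, bmm and Lk6, had a median of -0.23, at percentile 0.85 among 10000 random lists matched on mean signal. The groups overlapped for each of the 3 genes. Without group-housed replicate 3 bmm was at -0.084, and without group-housed replicate 2 Lip4 was at -0.021. With the deposited scaling the percentile of the median of these 3 genes was 4.47, inside the central 95%. Median centring shifts all probe sets of an array alike and so gives the same percentile. The result therefore depends on the scaling, rests on 3 genes, and leaves the hypothesis undecided.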
